A study of Homo sapiens with 2 samples.

How the data were processed

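Gene expression was measured on Affymetrix arrays in 2 stable derivatives of MDA-MB-231, a human triple-negative breast cancer cell line with mesenchymal features. One derivative carried an empty control vector and the other overexpressed the microRNA miR-203. There was 1 array per cell line. Per the labels' protocols, total RNA was purified on Qiagen columns and 6 µg was converted to biotinylated cRNA. The deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA, a method that corrects background, forces the arrays to one distribution and summarises each probe set by median polish; the version is not given in the sources used here. The log2 scale was inferred from the deposited values, which ran from 1.46 to 14.18 on the empty-vector array and from 1.37 to 14.23 on the miR-203 array. The sorted values of the 2 arrays differed by at most 0.095, with a median gap of 0.0093, as after quantile normalization. A shift of all mRNAs in one direction would be removed by this step. Of the probe sets, 6.40% held the same value on both arrays.

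Each array held 54675 probe sets, of which 62 were controls. The platform annotation used here gave exactly 1 gene symbol for 41091 probe sets, several for 1801, and did not list 11721. Symbols were checked against current RefSeq symbols through their gene identifiers. No gene was named from a probe set with several symbols. The 41091 probe sets represented 19775 genes. Each gene was given the probe set with the highest mean over the 2 arrays. RMA gives no detection calls, so a gene was kept if the higher of its 2 values was at or above 5.37, the median over all probe sets. This left 13311 genes, and 6464 did not pass.

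All differences are log2 of miR-203 minus log2 of empty vector. With 1 array per group there was no replicate error, so no test was made and no p-value is given. The number of arrays limits the precision, and a difference between the arrays includes culture, RNA preparation and hybridisation as well as miR-203. A gene was counted as higher or lower at a difference of 1 (2-fold) or more in size. Spread was described in 2 ways that do not replace replicates. One was the middle 95% of the differences of the 500 genes nearest in mean level. The other was the range of differences over the probe sets of a gene that passed the filter. In simulated data on the same 13311 genes, with noise of the robust spread seen here, 99 of 100 planted differences of 1.5 and 100 of 100 planted differences of 2 were recovered for this comparison, and 0 of 13111 unchanged genes were called. That noise model covers only the spread between genes on these arrays. With a threshold of 1 against an SD of 0.22 over all genes, the absence of false calls was nearly fixed in advance. It gives no false-call rate for the real data. The dimmest genes spread more widely, with a middle 95% of -0.64 to 0.61 around LINC01088. The filter itself widens this range, because a gene with a mean under 5.37 passes only if its 2 values differ. Around NLRC5, at 5.54 and 5.78, the range was -0.41 to 0.40.

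The rules for naming genes in the report, and 35 gene lists, were fixed before the data were examined. Named genes were the 12 highest and the 12 lowest that passed the filter, leaving out genes with another probe set past the filter of opposite sign, symbols starting with LOC or containing orf, and genes that inform on sex. Up to 5 members with the largest differences were named for each list that stood apart, and 9 published miR-203 targets were to be named whatever their value. For 24 list entries an older symbol was updated. A list's median was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression, and was said to stand apart below the 2.5th or above the 97.5th percentile. Lists with fewer than 5 genes passing were given values only. These percentiles describe the 2 arrays and are not tests of miR-203. By chance 1.7 of the 34 lists with a percentile would stand apart, if the genes within a list varied independently, as in the random lists. Members of a list that vary together for any reason would make more lists stand apart, so 1.7 is likely too low. Some lists share members, as the bone metastasis and protease lists share MMP1, so lists that stand apart are not separate outcomes.

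Alternatives were no filter, a filter at the 75th percentile of probe sets, the median over a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at (which can match several transcripts), removal of a loess trend (span 0.3), centring on the median, thresholds of 1.5-fold and 3-fold, and list means. Where 1 of a gene's 2 values lay under the filter level, that value was raised to it. The fold is then given as at least that large for the genes named with a fold. The filter level is not a detection limit, so such a fold is a convention and not a bound on the true difference. Planned comparisons of genes with miR-203 seed sites needed 3' UTR sequences, which were not used here. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.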

Results

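To find genes regulated by miR-203 in a breast cancer cell line, the expression profile of MDA-MB-231 cells that stably overexpressed miR-203 was compared with that of cells carrying an empty vector, with 1 array per line. The arrays had medians of 5.38 for the empty vector and 5.38 for miR-203 on the log2 scale, and correlated with r = 0.996 over 54675 probe sets. Of the 13311 genes that passed the filter, 96.9% differed by less than 0.5 on the log2 scale. Their differences had a median of 0.013, an SD of 0.22 and an interquartile range from -0.11 to 0.15. The 18 hybridisation control probe sets, which report transcripts added to every sample, differed by -0.19 to 0.11, and the 27 poly-A control probe sets, of which 26 lay under the filter level on both arrays, by -0.44 to 0.29. The difference between 3' and 5' probe sets, a sign of RNA integrity, was 1.38 for ACTB in the empty-vector line and 1.49 in the miR-203 line, and 0.11 and 0.049 for GAPDH. No probe set in the annotation was named for the miR-203 gene (0 of 54675), so overexpression itself was not measured on these arrays.

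The miR-203 line had 14 genes at least 2-fold higher and 36 genes at least 2-fold lower than the empty-vector line. The largest gain was in S100P, a calcium-binding protein of the S100 family, at 4.03-fold, and the largest losses among the named genes with both values over the filter level were in CCND2 (cyclin D2) and MMP1 (interstitial collagenase), at 4.42-fold and 4.18-fold. The loss of VAT1L was at least 3.41-fold, as its miR-203 value lay under that level. AGR2, a disulfide isomerase of the secretory pathway, was 3.12-fold higher, and IL24, a cytokine of the interleukin-10 family, was 3.32-fold lower. At 1.5-fold, 96 genes were higher and 144 lower, and at 3-fold, 3 were higher and 6 lower. Most of the 2-fold differences lay in the dimmer part of the genes, split at the median level. That part held 10 higher and 28 lower genes, against 4 higher and 8 lower in the brighter part. Among the dimmest genes the filter itself favours those whose 2 values differ. With 1 array per line none of these differences could be compared with replicate error.

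Among the 12 highest genes, S100P went from 6.31 in the empty-vector line to 8.32 in the miR-203 line, a log2 difference of 2.01, where the middle 95% of genes of similar level spanned -0.39 to 0.42. AGR2 went from 7.63 to 9.27, and its probe sets gave differences of 1.07 and 1.64. Versican (VCAN), a matrix proteoglycan, was 2.29-fold higher, with 5 probe sets between 0.75 and 1.20. ITM2A, a membrane protein, was 2.10-fold higher, with probe sets at 1.07 and 1.18. The interleukin-7 receptor gene IL7R was 2.12-fold higher, with probe sets at 0.71 and 1.09, and the median of its probe sets, 0.90, lay under the 2-fold threshold. The other named genes on this side had 1 probe set passing the filter. These were the long non-coding RNA LINC01088, SHOC1, a meiotic recombination gene, the zinc finger gene ZNF415, the G-protein regulator RGS7 (2.18-fold), S100G (2.14-fold), another S100-family calcium-binding protein, the fatty acid elongase ELOVL7 (2.11-fold), and the secreted glycoprotein reelin (RELN, 2.10-fold). LINC01088, SHOC1 and ZNF415 were below the filter level in the empty-vector line, at 4.46, 4.49 and 4.44, so that their gains were at least 1.74-fold, 1.36-fold and 1.08-fold and their 2-fold calls rest on values under that level.

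Among the 12 lowest genes, CCND2 went from 8.81 to 6.67, a difference of -2.14, and its second probe set gave -1.90. MMP1 went from 9.69 to 7.62, a difference of -2.07, where genes of similar level spanned -0.34 to 0.50. VAT1L went from 7.14 to 5.01, and the homeobox gene IRX1 from 6.01 to 4.20, so that the miR-203 values of both lay under the filter level, and the loss of IRX1 was at least 1.55-fold. IL24 went from 7.97 to 6.24. TIE1, an endothelial receptor tyrosine kinase, was 2.94-fold lower, CST7 (cystatin F, a protease inhibitor) 2.83-fold lower and AUTS2 2.68-fold lower. TMEM132D-AS1, an antisense transcript, was 2.64-fold lower, with probe sets at -1.40 and -1.38. GSPT2, a translation termination factor, was 2.37-fold lower and CORO2B, an actin-binding coronin, 2.35-fold lower. MMP1, VAT1L, IRX1, IL24, TIE1, CST7, AUTS2, GSPT2 and CORO2B each had 1 probe set passing the filter. HSPB8, a small heat shock protein, was 2.34-fold lower by its brighter probe set, but its other probe set gave -0.25 and the call was lost with the median of the probe sets, at -0.74.

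**Figure D1:**
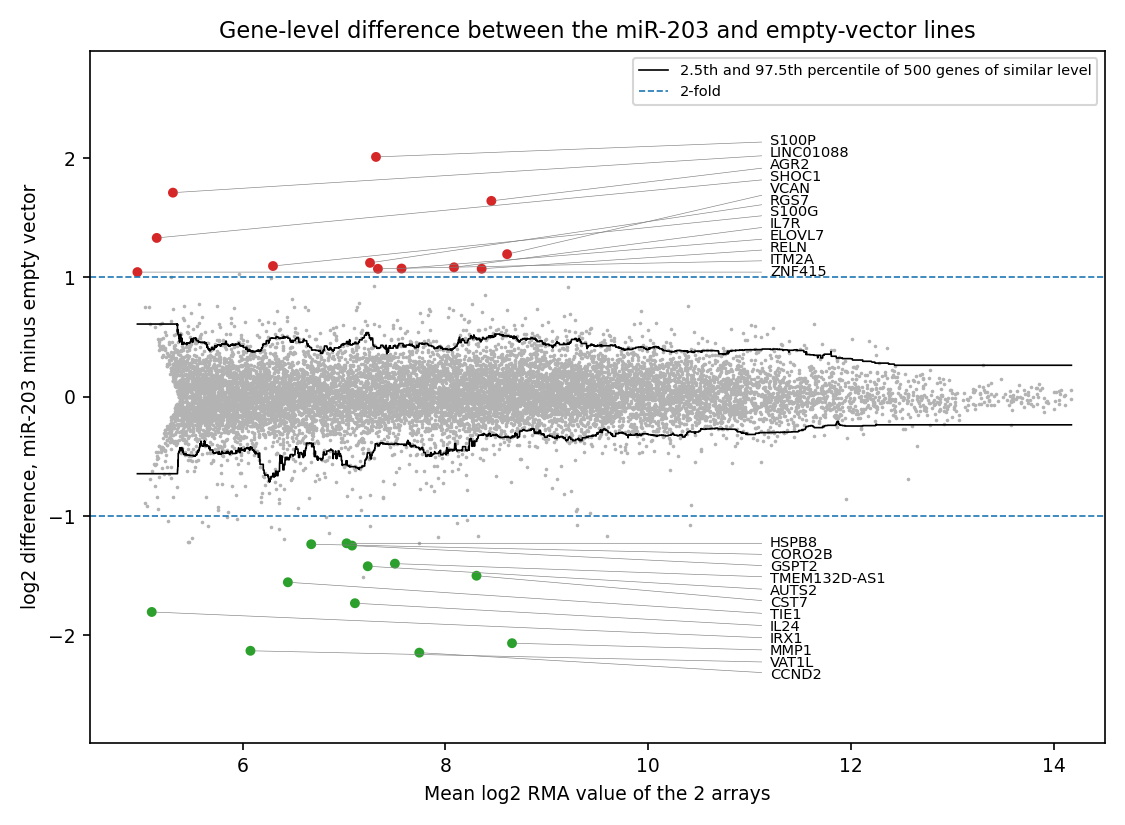
Each grey point is a gene that passed the filter, placed by its mean log2 RMA value over the 2 arrays (x axis) and its log2 difference, miR-203 minus empty vector (y axis). Red and green points are the 12 highest and 12 lowest named genes; black lines bound the middle 95% of the 500 genes nearest in level, dashed lines mark 2-fold, and S100P at 2.01 and CCND2 at -2.14 lie farthest out among the labelled genes.

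Over the genes measured by several probe sets, the SD of the difference within a gene had a median of 0.10 and a 95th percentile of 0.32 over 6286 genes. Of the 14 higher genes, 4 had another probe set passing the filter, and in 4 of the 4 all probe sets had the same sign and a difference of at least 0.5 in size. Of the 36 lower genes, 12 had another probe set passing, and in 7 all probe sets had the same sign, 4 of them with a size of at least 0.5. A same sign for all probe sets was found in 52.7% of all genes with several probe sets (exact binomial 95% interval 51.5 to 53.9%, counting error only), against 58.3% (27.7 to 84.8%) of the lower genes.

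Published targets of miR-203 were lower as a list, by a small amount. The 27 targets that passed the filter had a median difference of -0.12 (interquartile range -0.24 to 0.046), at the 0.03rd percentile of matched random lists, with 17 below 0 and 9 above. No target reached 2-fold (0 of 27), and 1 reached 1.5-fold. That gene was LASP1, an actin-binding LIM and SH3 protein, which went from 12.37 to 11.52, 1.81-fold lower in a range where the middle 95% of genes spanned -0.24 to 0.32. SNAI2 (Slug), a repressor of epithelial genes, had a difference of -0.46 where genes of similar level spanned -0.45 to 0.45. MSI2, an RNA-binding protein, was at -0.48 by its brightest probe set, with 7 probe sets from -0.99 to 0.22. Without the _x_at and _s_at probe sets its brightest gave 0.22, the opposite sign, while the others left past the filter gave 0.12 and -0.47. The kinase SRC was at -0.41, the transcription factor RUNX2 at -0.37, survivin (BIRC5) at -0.27 and ABL1 at -0.13. The second probe set of SRC gave a difference of 0 and that of RUNX2 0.029. ZEB2, whose miR-203 value lay under the filter level, was at -0.37. This lay inside the -0.64 to 0.61 of genes of similar level, a range widened by the filter. With its miR-203 value raised to the filter level ZEB2 was at -0.16. Its other probe sets, all under the filter level, gave differences from 0.021 to 0.37. CAV1 (caveolin-1) and SMAD1 lay on the other side, at 0.16 and 0.096, as did ZNF217 at 0.47. BMI1, the remaining target to be named, was not analysed here. Without the _x_at and _s_at probe sets the median of the list was -0.060, at the 2.86th percentile, and the list no longer stood apart.

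Genes linked to bone metastasis of breast cancer had the lowest median of the lists with a percentile, -0.24 over 11 genes (interquartile range -0.38 to 0.072), below all 10000 random lists. MMP1 was the member past 2-fold. CXCR4, a chemokine receptor, was 1.55-fold lower, with 3 probe sets from -0.63 to -0.40, and lysyl oxidase (LOX) was at -0.40 and -0.069 by 2 probe sets. The Notch ligand JAG1 and the phosphatase DUSP1 were higher, at 0.39 and 0.50, and the 2 dimmer probe sets of DUSP1 gave the opposite sign, to -0.20. Matrix proteases and their inhibitors had a median of -0.11 over 18 genes, at the 0.23rd percentile, with MMP1 again the member past 2-fold. The membrane protease MMP14 was at -0.38, with 4 probe sets from -0.58 to -0.25, ADAMTS1 at -0.35 and -0.80 by 2 probe sets and urokinase (PLAU) at -0.29, while ADAM9 was at 0.45 by its brightest probe set and at 0.046 and 0.12 by the others. The protease list no longer stood apart without MMP1, with a median of -0.078 at the 3.76th percentile, or without the _x_at and _s_at probe sets, at the 4.49th.

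Collagen and matrix glycoprotein genes had a median of 0.13 over 20 genes, at the 98.88th percentile, with 11 above 0 and 9 below. VCAN was the member past 2-fold. Fibronectin (FN1) was 1.49-fold higher, with 5 probe sets between 0.47 and 0.62. Thrombospondin-1 (THBS1) was at 0.49 by the brightest of 4 probe sets that ran from 0.14, and the collagen gene COL8A1 was at 0.39. COL5A2, whose empty-vector value lay under the filter level, was at 0.48, inside the -0.50 to 0.49 of genes of similar level. With that value raised to the filter level it was at 0.39, and its other probe set, under the filter level, gave -0.069. Without VCAN the median of the list was 0.095, at the 94.04th percentile, and the list no longer stood apart. TGF-beta and BMP pathway genes had a median of 0.11 over 29 genes, at the 98.5th percentile, with 19 above 0 and none past 2-fold (0 higher, 0 lower). The growth factor TGFB2 was 1.65-fold higher, with 4 probe sets from 0.26 to 0.82, and PMEPA1, a feedback gene of the pathway, 1.63-fold higher, with 3 probe sets from 0.41 to 0.70. SMAD6 was at 0.54. ID2, a target of BMP signals, was 1.79-fold lower. SMAD9, with its miR-203 value under the filter level, was at -0.59. This lay inside the -0.64 to 0.61 of genes of similar level, a range widened by the filter. With its miR-203 value raised to the filter level SMAD9 was at -0.18. This list no longer stood apart when the median over probe sets was used, at the 90.7th percentile, or the mean of members, at the 90.2nd, and without the _x_at and _s_at probe sets its median was 0.039, at the 65.8th.

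Epithelial junction and keratin genes had a median of -0.11 over 22 genes, at the 0.57th percentile. KRT19 was 2.10-fold lower, KRT7 was at -0.58 and -0.12 by 2 probe sets and desmoplakin (DSP) was at -0.33. The tight junction gene MARVELD2 was at -0.49, at the edge of the -0.49 to 0.45 of genes of similar level. Its miR-203 value lay under the filter level, and with that value raised to it the difference was -0.30. Occludin (OCLN) was higher at 0.39, with 3 probe sets from 0.27 to 0.46. The sign of this list depended on the probe sets: without those ending in _x_at and _s_at its median was 0.014, at the 47.3rd percentile. Mesenchymal and EMT genes had a median of -0.028 over 22 genes, at the 21.1st percentile, and under the same setting -0.12, at the 1.87th, so that this list then stood apart as lower.

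Immediate early and MAPK feedback genes were slightly lower as a list, with a median of -0.14 over 24 genes at the 0.01st percentile and 18 of 24 below 0. No member reached 1.5-fold (0 higher, 0 lower). The phosphatases DUSP6 and DUSP5 were at -0.41 and -0.24, the former with 3 probe sets from -0.41 to -0.11, SPRY1, an inhibitor of growth factor signals, at -0.28 and IER2 at -0.23, against 0.50 for DUSP1 by its brightest probe set. The 6 metallothionein genes, which encode metal-binding proteins, were all below 0, with a median of -0.21 at the 0.01st percentile. MT1F was at -0.41, MT1H at -0.24, MT1X at -0.23, MT1G at -0.19 and MT1E at -0.15. These genes are near-identical copies measured by probe sets that can match several of them, so they are not independent measurements. Their percentile also does not allow for position on a chromosome, on which the random lists were not matched. MHC class I and antigen presentation genes had a median of -0.097 over 14 genes, at the 1.01st percentile. The immunoproteasome subunit PSMB9 was 1.51-fold lower, HLA-B was at -0.46, with 3 probe sets from -0.46 to -0.26, and HLA-C at -0.27, again by probe sets that can match related genes, while the peptidase ERAP1 was at 0.39 by its brighter probe set and at -0.062 by the other, and the activator NLRC5 at 0.25. Without PSMB9 this list had a median of -0.069, and without the _x_at and _s_at probe sets -0.066, at the 11.6th percentile, and under neither did it stand apart. NRF2 targets, genes of the antioxidant response, had a median of 0.15 over 14 genes at the 99.1st percentile, but the list no longer stood apart as a mean, 0.066 at the 80.3rd percentile, without the filter, with a median of 0.070 at the 85.3rd, or with the stricter filter, at the 97.37th. The cystine transporter SLC7A11 was at 0.42, AKR1C1 at 0.22, ME1 at 0.19 and 0.37 by 2 probe sets and AKR1C3 at 0.18, and thioredoxin reductase TXNRD1 was lower at -0.54.

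The other 24 lists with a percentile did not stand apart. Cell cycle and mitosis genes had a median of -5.5e-06 over 38 genes, at the 30.2nd percentile, with 19 above 0 and 19 below. Interferon-stimulated genes had a median of 0.018 (55.8th percentile), p53 target genes -0.020 (22.8th), Wnt pathway genes -0.023 (21.2nd), YAP and TEAD targets 0.024 (58.5th), and NF-kB targets and cytokines 0.096 (95.1st). Integrin and focal adhesion genes were at -0.038 (9.85th), actin cytoskeleton genes at -0.035 (9.88th), receptor tyrosine kinases and ligands at 0.0023 (40.9th), apoptosis regulators at -0.048 (7.45th), and microRNA processing and Argonaute genes at -0.012 (28.2nd). Hypoxia and glycolysis genes were at 0.065 (92.5th), cholesterol synthesis genes at 0.058 (77.2nd), ATF4 and unfolded protein response genes at -0.054 (3.18th), heat shock genes at 0.036 (75.1st), oxidative phosphorylation genes at -0.037 (9.35th), ribosomal protein genes at -0.032 (14.6th), core histone genes at -0.052 (16.0th), and commonly used reference genes at 0.0096 (51.3rd). Keratinocyte differentiation genes, of which 6 passed the filter, were at -0.13 (7.66th), and MHC class II genes, of which 5 passed, at -0.016 (42.9th). Of the markers of other cell types, the luminal breast list had a median of -0.0019 over 14 genes (39.9th), although its members AGR2 and ELF3 were higher by 1.64 and 0.72. The blood cell and endothelial list had a median of -0.090 over 5 genes (21.3rd), with KDR at -0.75 but its miR-203 value, 4.76, under the filter level. The 4 fibroblast markers that passed the filter had a median of -0.061, with THY1 at -0.84.

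**Figure D2:**
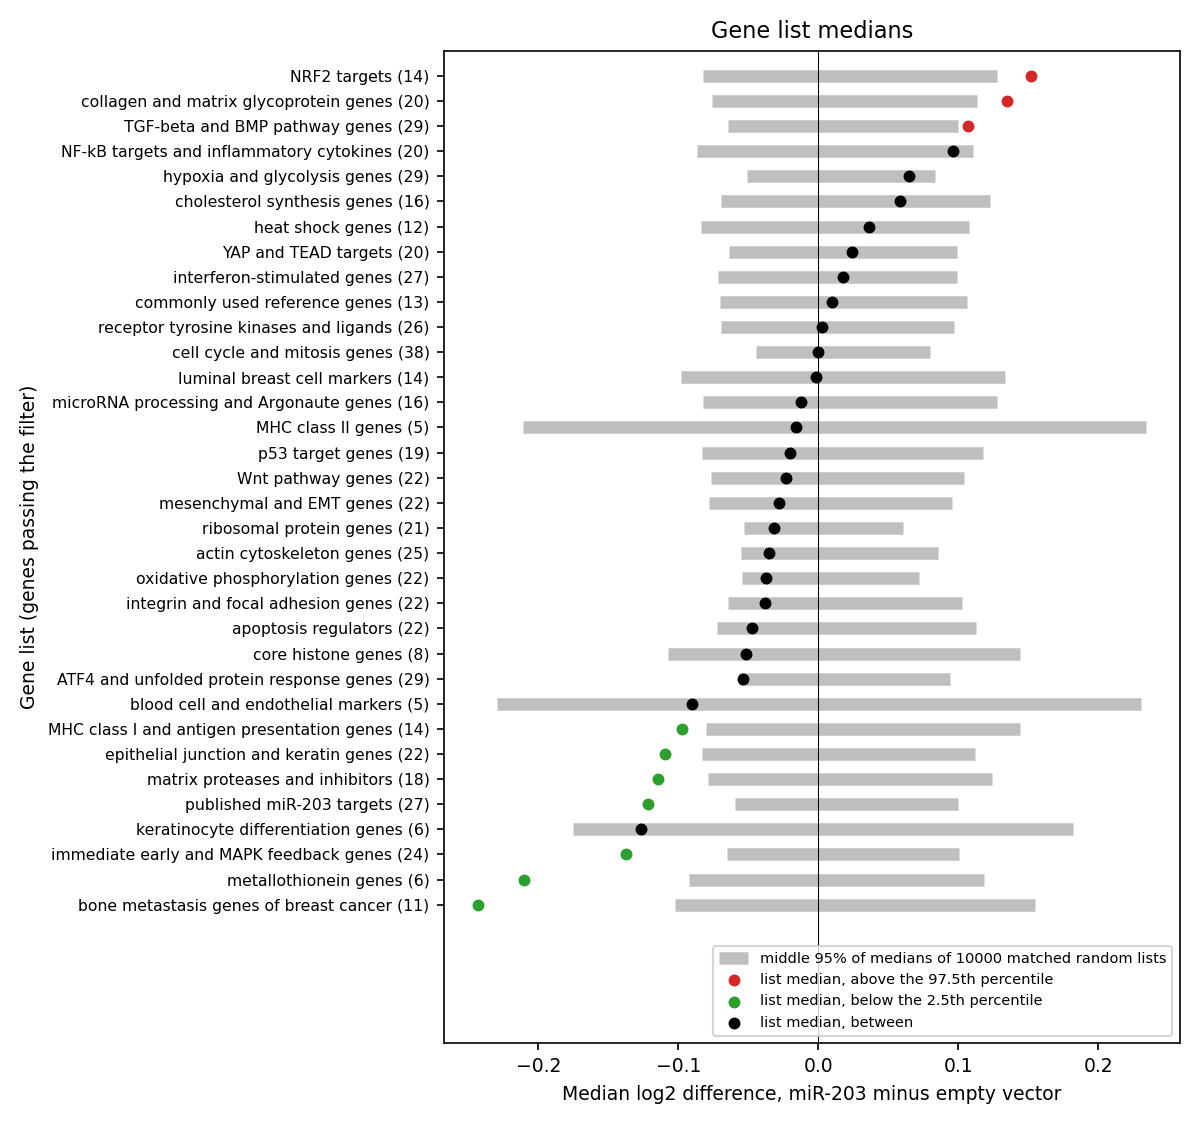
Each point is the median log2 difference, miR-203 minus empty vector (x axis), of the genes of a list fixed in advance (y axis, number of genes passing the filter in brackets). Grey bars span the middle 95% of medians of 10000 random lists matched on mean expression; 7 lists lie below their bar, from -0.24 for bone metastasis genes, and 3 lie above, up to 0.15 for NRF2 targets.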

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

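With 1 array per line no replicate could be left out, and no paired analysis was possible because each group held 1 sample. Comparisons of seed-site genes were not run. The counts of genes 2-fold higher and lower, 14 and 36, were 8 and 20 with the filter at the 75th percentile, 96 and 144 at 1.5-fold and 3 and 6 at 3-fold, as fewer or more genes could pass. The counts moved by less than 1.5 times under the other alternatives run, from 10 to 16 higher and from 28 to 43 lower; the lowest, 10 and 28, came with values under the filter level raised to it, chosen after seeing the data. Of 34 lists, 10 stood apart, and between 8 and 12 did so under the alternatives other than leaving out _x_at and _s_at probe sets, which left 6. That setting gave medians of -0.060 for published miR-203 targets, 0.014 for epithelial genes (a change of sign), -0.078 for matrix proteases, -0.066 for MHC class I genes and 0.039 for TGF-beta and BMP genes, none of which then stood apart; it left too few metallothionein genes for a percentile. The cause was not tested. Another alternative chosen after seeing the data left out the member with the largest difference: proteases then had -0.078, collagen and matrix genes 0.095 and MHC class I genes -0.069, and none of the 3 stood apart. TGF-beta and BMP genes had 0.063 with the median over probe sets and 0.071 as a mean, and did not stand apart under either. NRF2 targets had 0.070 without the filter, 0.143 with the stricter filter and 0.066 as a mean, and did not stand apart under any of these. The lists of bone metastasis and immediate early genes stood apart under every alternative run. With values raised to the filter level, the named genes IRX1, LINC01088, SHOC1 and ZNF415 fell short of 2-fold, at -0.63, 0.80, 0.45 and 0.11. Of 281 values of named genes under the probe-set and normalization alternatives, 275 kept their direction and side of the 2-fold threshold, 3 fell short of it (HSPB8 under 2 settings and IL7R under 1) and 3 changed sign in genes short of 2-fold: DUSP1 was at -0.14 with the median of probe sets, and MSI2 and ERAP1 were at 0.22 and -0.062 without _x_at and _s_at probe sets. Of 184 values of the lists that did not stand apart, 10 stood apart under an alternative. Lower were mesenchymal and EMT genes (1.87th percentile without _x_at and _s_at probe sets), MHC class II genes as a mean (0.62nd), and single settings or more of the integrin, ATF4 and apoptosis lists. Higher were hypoxia and glycolysis genes, as a mean (99.8th) and without _x_at and _s_at probe sets (98.6th). Luminal markers as a mean (97.9th) and NF-kB targets without the largest member (97.8th) were also higher. Under the stricter filter the brighter genes alone remain, where signal lies farther over background.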

Other observations

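The genes in this and the next paragraph were chosen after their values were seen. Among ligands of the EGF receptor, EREG was 1.65-fold higher, with probe sets at 0.25 and 0.72, and TGFA was 1.61-fold higher by its brighter probe set but at -0.033 by the other. HBEGF was 1.97-fold lower by its brightest probe set, while its 3 probe sets ran from -1.16 to 0.25. DICER1, which encodes the ribonuclease that cuts microRNA precursors, was 1.64-fold higher, with 3 probe sets from 0.26 to 0.71, and the Argonaute genes AGO4 and AGO3 were at 0.54 and 0.41, while AGO2 and AGO1 were at -0.26 and -0.19 and TNRC6C and TNRC6B at -0.28 and -0.26; their list had 8 genes above 0 and 8 below and did not stand apart (28.2nd percentile).

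LCP1, an actin-bundling protein of leukocytes, was 2.25-fold lower, BCL2A1, a survival gene of the BCL2 family, 2.29-fold lower, and IFITM1, an interferon-induced membrane protein, 2.08-fold lower. The invariant chain gene CD74 was 2.84-fold lower by its brighter probe set and at 0.11 by the other. Of 4 cancer-testis genes, XAGE2 was 1.79-fold lower and MAGEB2 1.57-fold higher, and PRAME and CT75, whose miR-203 values lay under the filter level, were at least 1.65-fold and 1.33-fold lower. FKBP5, a target of steroid receptors, was 1.94-fold lower, with 3 probe sets from -0.96 to -0.70. Outside the named genes, 4 of 1132 probe sets with several gene symbols and 1 of 3096 not listed in the annotation were at least 2-fold lower, and 0 of either kind were 2-fold higher.

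In the tests that follow, the median of the other probe sets and the count of published targets were chosen after the results were seen, as were 2 rules: one leaves the share of genes with probe sets of 1 sign undecided because of its wide interval, and the other leaves the ratio after loess removal undecided because the trend removed was small. There were 36 genes 2-fold lower against 14 higher, a ratio of 2.57. An array-wide normalization bias toward lower values cannot be told apart. The ratio was 2.64 once the loess trend was removed, but that trend was at most 0.031 in size in values already quantile normalized. A shift of all genes by 0.09 would be needed to bring the ratio under 1.5. Centring on the median gave 13 higher and 36 lower. It cannot decide either, because the median it removed was 0.013, less than 0.09. For a copy number or regional difference between the 2 stable lines, 1 pair of the lower genes, MMP1 and ARHGAP42, lay within 5 genes of each other on a chromosome. As 1000 shuffles of gene order gave up to 4 pairs, the lower genes were not clustered beyond chance. A regional shift that carries only single genes past 2-fold would not show in this count. Listed miR-203 targets made up 0 of the 36 lower genes, so these genes add nothing to the count. That outcome was already known, and only 27 of 13311 genes were listed. The count therefore cannot decide whether lowering of miR-203 targets in general accounts for the difference. The list median was low (0.03rd percentile), as this explanation needs, but that need was also written after the results were seen. Without the _x_at and _s_at probe sets the list was at the 2.86th percentile and did not stand apart. Unlisted targets stay open. For the 12 lower genes with several probe sets, noise of single probe sets was argued against as the whole of their difference. The mean per gene of the probe sets that had not entered the call had a median of -0.53. The upper bound of a bootstrap 95% interval over genes was -0.15, and the mean lay below 0 in 10 of 12. These values cannot tell whether noise carried the 12 genes past 2-fold, because -0.53 is short of that threshold. All probe sets had the same sign and a size of at least 0.5 in 4 of the 12. For the other 24 genes noise cannot be told apart, with 1 probe set each. The share of the 12 genes with all probe sets of 1 sign was 58.3% (95% interval 27.7% to 84.8%), near the 52.7% of all genes with several, which is what noise would give and was the outcome foreseen for it; it was first read that way, and left undecided only once the width of the interval was seen; a difference between cultures or clones unrelated to miR-203 stays open as well.

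The differences of genes that neighbour each other on a chromosome correlated. Over 13296 genes in their order on the GRCh38.p14 assembly, adjacent genes correlated with r = 0.127, where the highest of 1000 shuffles of gene order gave 0.028; this is across genes, which are not independent replicates. Overlapping or shared probes of adjacent genes are argued against as the whole cause, because genes 10 apart still correlated with r = 0.071 and the highest shuffle gave 0.028. A gain or loss of large chromosome segments in 1 of the 2 lines is a candidate explanation: 3 of 253 windows of 50 neighbouring genes had a median difference beyond 0.2 in size, the highest 0.22 and the lowest -0.14. The largest size of a window median in 1000 shuffles was 0.17, and 17 of the 253 windows lay beyond that size. Probe GC content, which also varies by region, was not tested and stays open. The random gene lists were matched on expression and not on position. For a gene list whose members lie close together, the percentile therefore does not allow for this correlation, and a regional shift could set such a list apart. The lists that stood apart, among them the metallothionein and MHC class I lists, were not checked for this.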
